A study of Mus musculus with 15 samples.

How the data were processed

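The data are 1 table of 45101 probe sets on 15 Affymetrix mouse arrays. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on RNeasy columns, and 100 ng was amplified in a 2-cycle protocol to biotin-labelled cRNA. Amplification of this kind starts at the 3′ end of transcripts, so shortened RNA lowers probe sets that lie far from it. The deposited values are linear intensity values, 1 per probe set and array. The submitters' processing notes name Affymetrix Expression Console and PLIER, a model that combines the probes of a set, and give no version. The settings, the background correction and any scaling between arrays are not given in the sources used here. The array medians lay close together, at 61.2 to 71.7, and the upper tails did not, where the intensity that 1 in 20 probe sets exceeded was 867 to 2120, so the deposited intensities had not been brought to a common distribution. A shift in the upper tail moves bright genes in 1 direction, which is why results were repeated after quantile normalization.

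Groups were taken from the labels, which name mouse 1 to 15 as separate animals. The 5 groups are untreated, saline day 1, NTHi day 1, saline day 7 and NTHi day 7, with 3 arrays each. Replicate numbers were taken from the labels, and arrays were treated as unpaired.

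Values were used as log2(intensity + 16), the offset commonly used with PLIER. The 64 Affymetrix control probe sets were left out of all tests and used only to describe the arrays. Of the other 45037 probe sets, the platform annotation gives 1 gene symbol for 34945, several for 932 and none for 9160, and only the first kind was used. Symbols were checked through their gene ID against a RefSeq gene table of assembly GRCm38.p6, which changed 0 of them. No coordinates are given, because the array values name no genome build. This left 18193 genes, of which 9010 had several probe sets. The probe set with the highest mean over all 15 arrays stood for the gene, and 100 genes were represented by a set of the kind that can hybridise with related transcripts. Where as many or more probe sets of a called gene went the other way, this is stated.

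Genes were tested with limma 3.58.1 in R 4.3.3, with a mean per group in 1 fit over all arrays and moderated variances with an intensity trend (lmFit and eBayes). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all 18193 genes. The comparisons were NTHi against saline at day 1 and at day 7, the difference between these effects, saline against untreated at each day, and each treatment over time. NTHi against untreated at each day was added after the data were examined. Differences between comparisons that share arrays are not summarised as correlations or overlaps.

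Before the data were examined, 32 gene lists were fixed from textbook knowledge of mucosal inflammation, mucous metaplasia, and the cell types that a middle ear dissection can carry. They held 606 distinct genes, of which 557 were measured and the rest were not analysed here. Lists overlap in part. They were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, and adjusted over the 32 lists. Camera with an estimated correlation and fry, which tests whether a list moves on balance in 1 direction without comparing it with other genes, were run beside it. Members are counted over all genes and adjusted over the list alone. Of 111 list calls over all comparisons, 1 had a median or mean of the other sign, that of mast cell, eosinophil and basophil markers in saline day 7 against saline day 1 (upward, adjusted p = 0.0479, median -0.04), which ended at adjusted p = 0.471 with an estimated correlation.

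The genes named were also chosen by a rule fixed before the data were examined. It took the 10 largest rises and falls among passing genes without overlap between groups in each NTHi comparison, 5 of each for the difference between days and 4 of each elsewhere, and filled up to 5 by the smallest p where fewer passed. It added up to 4 passing members of each list, of which at most 2 are named here, or the member with the largest change where none passed. A fixed set of genes (Cxcl2, Cxcl1, Il1b, Tnf, Il6, Tlr2, Tlr4, Muc5ac, Muc5b, Muc4, Lcn2, S100a8 and Saa3) was always included. Genes that are known by an unnamed model symbol were left out.

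The calculations were tested on simulated data for 18193 genes, with each gene's mean over all 15 arrays and its residual spread in the fit of 5 groups. Changes were planted in the NTHi day 7 group, which was then compared with the untreated group. At a log2 change of 1, 25 of 57 changed genes were recovered (43.9%), at 2, 64 of 68 (94.1%), and at 3, 74 of 75 (98.7%). Of 186 calls, 9 were members of a planted list of 20 genes with a log2 change of 1, and 14 were false (7.53%). The planted list passed at adjusted p = 3.44e-30 and 0 of the 32 other lists did. As the simulated genes did not correlate, this does not show how the list test behaves on real arrays.

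The alternatives fixed in advance were quantile normalization, a common median, an offset of 1, keeping the upper 50% of probe sets by mean, no intensity trend, array quality weights, the mean of a gene's probe sets, a test per probe set, a fit on the compared groups only, a block for the replicate number, each array left out in turn, and a further threshold of 2-fold. A fit without the saline day 7 group and a fit with the mean level of the skeletal muscle markers as a covariate were added after the data were examined, as were all alternatives for NTHi against untreated.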

Results

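Gene expression was profiled on 15 Affymetrix mouse arrays, 1 per animal, in middle ear tissue of adult Balb/c mice, an inbred laboratory strain. The submitters name the tissue as epithelial cells of the middle ear. Nontypeable Haemophilus influenzae (NTHi) is an airway bacterium and a common cause of otitis media. A sonicated lysate of it at 300 µg/ml, or buffered saline, was inoculated through the eardrum in 50 µL, and arrays were made at day 1 and day 7. The 5 groups held 3 mice each: untreated, saline day 1, NTHi day 1, saline day 7 and NTHi day 7. The protocol describes 3 weekly injections with a harvest on day 28, and the labels do not say how many of these the mice on the arrays had received. Levels are log2(intensity + 16), with a floor of 4, and changes are log2 fold changes on that scale, which understates the change of dim genes. Changes are given with their standard error (SE, n = 3 arrays per group) from 1 limma fit over all 15 arrays. The small number of arrays limits the precision.

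The saline day 7 arrays stood apart from the other 12 arrays in several array measures. Their summed intensity was 8880110 to 10935000, against 16744100 to 20161400 on the others. The cre control, a phage transcript spiked into the hybridisation, had a level of 11.64 to 12.35 on them and 13.07 to 13.71 elsewhere. Of the other spike-ins, bioD was also apart (10.34 to 11.02 against 11.09 to 12.57), while bioC (9.11 to 9.61 against 8.86 to 10.66) and bioB (8.08 to 8.49 against 7.42 to 9.17) overlapped. The 5′ actin probe set lay further below the 3′ one on them, by a log2 difference of -5.27 to -4.59, against -3.61 to -0.45 on the others, where the lowest value belonged to saline day 1 replicate 1. The same difference for Gapdh was -2.80 to -2.69 against -2.55 to -1.50. Within groups, arrays correlated across genes with r from 0.928 to 0.989, and 0 of the arrays of a group held identical values.

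**Figure D1:**
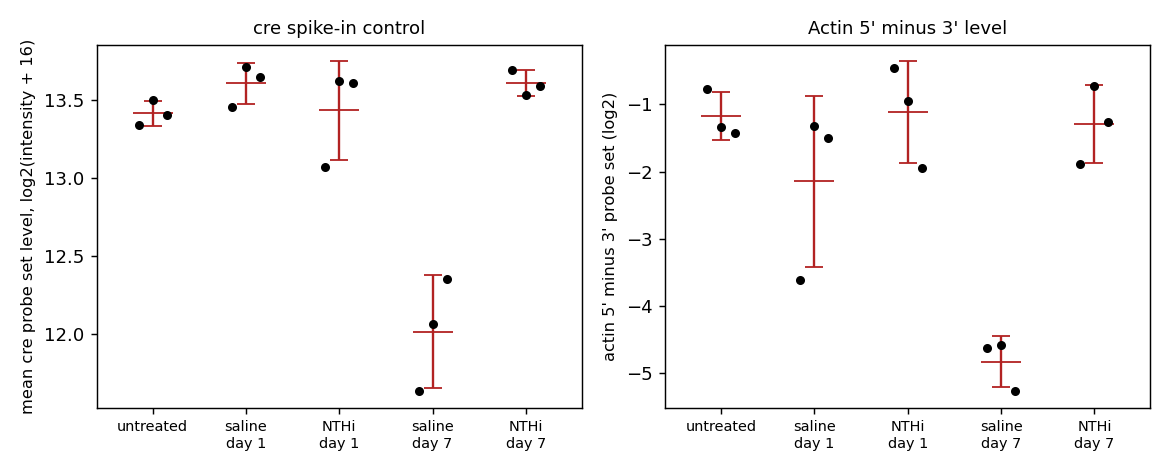
Left, level of the cre spike-in control, log2(intensity + 16), per array; right, log2 level of the 5′ minus the 3′ actin probe set. Points are arrays, and red bars are the group mean ± SD (n = 3). The saline day 7 arrays lie below all other 12 arrays in both panels, at 11.64 to 12.35 and at -5.27 to -4.59.

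Saline day 1 was compared with untreated arrays to measure what the inoculation itself changed. Saa3, an acute phase protein, rose by 4.76 ± 0.65 (adjusted p = 0.0374), from a level of 5.59 ± 0.67 to 10.36 ± 1.32 (SD, n = 3). Cxcl2, a neutrophil-attracting chemokine, rose by 4.40 ± 0.50 (adjusted p = 0.00902), from 6.67 ± 0.22 to 11.07 ± 0.30 (SD, n = 3). Prss21, a serine protease, rose by 1.27 ± 0.18 (adjusted p = 0.0374). Each of these was higher in 3 of 3 saline arrays than in any untreated array, as the rule for naming genes required. S100a8, a neutrophil calprotectin subunit, had a change of 3.47 ± 0.57 (adjusted p = 0.0814), and Il1b one of 2.41 ± 0.66 (adjusted p = 0.165). These 3 rises and 0 falls were all the genes past the threshold among 18193 tested. In all 2820 genes, these 3 among them, had an unadjusted p under 0.05, and 4832 genes (26.6%) had groups that did not overlap, where chance gives 10%.

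Of the 32 gene lists, 15 passed limma's camera test in this comparison, 13 upward, and none of these calls held, the smallest being adjusted p = 0.678 with an estimated correlation. Mature neutrophil markers led the rises (median 1.70, adjusted p = 4.19e-06), with 0 of 13 members past the threshold over all genes and 5 that rose when adjusted over the list alone. Cell cycle genes (median 0.47, adjusted p = 4.19e-06) had 0 of 26 members past it either way. Among the antimicrobial and acute phase genes (median 0.31, adjusted p = 0.00612), Saa3 rose, and 5 rose and 2 fell when adjusted over the list alone. Among the 7 genes of the list of neutrophil-attracting CXC chemokines and their receptors (median 1.00, adjusted p = 0.00638), Cxcl2 rose. Skeletal muscle markers (median -1.70, adjusted p = 8.50e-05) and motile cilia genes (median -0.83, adjusted p = 1.25e-04) moved downward as lists, with 0 members past the threshold. The mean centred level of the muscle list overlapped between the groups. It was -1.14, 1.01 and 1.19 on saline day 1 arrays and 3.15, 0.73 and 1.61 on untreated ones. Quantile normalization left Saa3 at 4.73 and Prss21 at 1.28, no longer past the threshold. The count was 0 without saline day 1 replicate 1, untreated replicate 2 or untreated replicate 3, 1 without saline day 1 replicate 2, 6 without saline day 1 replicate 3, and 2 without untreated replicate 1, where Saa3 did not pass. With array weights 321 genes rose and 1400 fell.

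NTHi day 1 against saline day 1 asked what the lysate added to the inoculation after 1 day. The values with the smallest p were those of Pglyrp1, a peptidoglycan-binding protein of granulocytes, at 1.90 ± 0.30 (adjusted p = 0.397), and of Kera, a proteoglycan of stromal matrix, at -2.55 ± 0.46 (adjusted p = 0.622). Cfb, complement factor B, was at 2.60 ± 0.59, Fpr2, a formyl peptide receptor of neutrophils, at 2.98 ± 0.87, and Saa3 at 2.36 ± 0.65 (adjusted p = 0.991 for each). None of the 18193 genes passed in limma. The count at an unadjusted p under 0.05 was 798, against 910 by chance, and 1383 genes (7.60%) had groups that did not overlap, against the 10% of chance. The remaining genes of smallest p were Ikbke at 1.31, Slc39a4 at 1.17 and Cdk2ap2 at 1.02 among the higher, and Kif5c at -1.11, Nkd2 at -0.95, St6galnac1 at -0.93 and Prox1 at -0.76 among the lower. Cdk2ap2 had 1 of 2 probe sets in that direction. The counts changed to 4 genes, all higher, without NTHi day 1 replicate 2, and to 1 without saline day 1 replicate 1, where Kera passed at -3.19.

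As lists, 12 moved upward and 5 downward at day 1, each relative to the other genes and with 0 members past the threshold over all genes. None of these calls held, the smallest being adjusted p = 0.177 with an estimated correlation. Antimicrobial and acute phase genes had a median of 0.91 (adjusted p = 8.99e-11), and 3 of 24 rose when adjusted over the list alone. Lcn2, an iron-scavenging lipocalin, was at 1.27 and S100a8 at 0.98. Mature neutrophil markers had a median of 1.45 (adjusted p = 1.08e-08), with 4 of 13 up when adjusted over the list alone. Toll-like receptor and NF-kB feedback genes had a median of 0.60 (adjusted p = 4.28e-08), with Irak3 at 1.41, Tlr2 at 1.07 and Tlr4 at 0.33. Interferon response genes had a median of 0.75 (adjusted p = 5.00e-08), with Cxcl10 at 1.83 ± 1.08. The 7 neutrophil-attracting CXC chemokines and receptors had a median of 1.05 (adjusted p = 2.19e-04), with the neutrophil receptor Cxcr2, also a member of the neutrophil list, at 1.82, Cxcl2 at 1.00 and Cxcl1 at 0.93. Monocyte and lymphocyte chemokines (median 0.63, adjusted p = 0.0104; Ccl3 at 2.25) and complement genes (median 0.61, adjusted p = 2.19e-04) each had 1 member up when adjusted over the list alone. Monocyte and macrophage markers had a median of 0.60 (adjusted p = 0.00168), with Clec4e at 2.48 ± 0.88.

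Epithelial lists, whose calls likewise ended (the smallest at adjusted p = 0.532 with an estimated correlation), moved upward by less: simple and secretory genes by a median of 0.31 (0.20 after quantile normalization, adjusted p = 0.00168; Sftpd at 1.53), motile cilia genes by 0.33 (adjusted p = 0.00557; Tekt1 at 0.71) and mucins and goblet cell genes by 0.24 (adjusted p = 0.0173). Of the mucins themselves, Muc5b was at 0.73 ± 0.65, Muc4 at 0.72 ± 0.33 and Muc5ac at 0.23 ± 0.71, and none passed. Cell cycle genes had a median of 0.36 (adjusted p = 0.0206; Nusap1 at 0.61). The downward lists were skeletal muscle markers (median -1.03, adjusted p = 2.30e-06; Myh1 at -1.96), bone cell markers (median -0.81, adjusted p = 5.49e-05; Dmp1 at -1.77), erythroid markers (median -0.26, adjusted p = 0.00168), fibroblast and extracellular matrix genes (median -0.46, adjusted p = 0.00168; Col1a1 at -1.47) and adipocyte markers (median -0.53, adjusted p = 0.00978). The fall of muscle markers accompanied the rises above, and the muscle score, the mean centred level of the list, differed among the saline arrays, at -1.14 on replicate 1 and 1.01 and 1.19 on the others. All 17 calls ended with an estimated correlation, from adjusted p = 0.177 to adjusted p = 0.751 with an estimated correlation, and fry, which tests a list on its own, passed 0.

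The other 15 lists did not pass at day 1. They were pro-inflammatory cytokines and receptors, basal and squamous epithelial genes, granulocyte precursor, T and NK cell, B and plasma cell, and mast cell, eosinophil and basophil markers, cartilage, endothelial, Schwann cell and neuronal, and inner ear markers, matrix metalloproteinases and inhibitors, MHC class II and antigen presentation genes, EGFR ligands and epithelial repair genes, immediate early genes, and hypoxia and glycolysis genes (adjusted p = 0.0652 to 0.855). Among them Il1b was at 1.90 ± 0.66, Tnf at 1.78 ± 0.70 and Il6 at -0.04 ± 0.67. T and NK cell markers had a positive median (0.10) and mean (0.06) but a downward test, and the mean of the B and plasma cell markers (0.03) also opposed its median (-0.05) and test.

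NTHi arrays were also set against untreated arrays, a comparison added after the data were examined that holds lysate and inoculation together. At day 1, Saa3 rose by 7.13 ± 0.65 (adjusted p = 3.77e-04), to 12.72 ± 1.11 (SD, n = 3). Cxcl2 rose by 5.39 ± 0.50 (adjusted p = 3.77e-04) and Slfn4, an interferon-induced gene of myeloid cells, by 6.00 ± 0.70 (adjusted p = 0.00404). Acod1, the itaconate-producing enzyme of activated macrophages, rose by 5.60 ± 0.89 (adjusted p = 0.0378), and Il1b by 4.31 ± 0.66 (adjusted p = 0.0322). The neutrophil markers S100a9, S100a8, Clec4d and Trem1 rose by 4.75, 4.44, 4.33 and 3.93, and the chemokine Ccl3 by 4.52. All 3 NTHi arrays lay above all 3 untreated arrays in each of these 10 genes, as the rule for naming genes required. In all 11 genes rose and 0 fell. There were 2170 genes, these 11 included, with an unadjusted p under 0.05, and 3710 (20.4%) did not overlap, against 10% by chance. The count was 97, 81 of them higher, without NTHi day 1 replicate 2. It was 3 without NTHi day 1 replicate 1 or 3 or untreated replicate 3, 5 without untreated replicate 1, 6 after quantile normalization, and 0 with the muscle level as a covariate. With array weights 94 genes rose and 78 fell. Under quantile normalization Acod1, Ccl3, Clec4d and Il1b were at 5.42, 4.36, 4.18 and 4.15 and no longer passed.

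Of the lists, 19 passed against untreated arrays at day 1, 14 of them upward. None held, the smallest value, of the neutrophil-attracting CXC chemokines and receptors, being adjusted p = 0.0528 with an estimated correlation, while fry passed 3 lists. Mature neutrophil markers had a median of 3.36 (adjusted p = 8.60e-18), with 5 of 13 members that rose and 10 that rose when adjusted over the list alone. Antimicrobial and acute phase genes had a median of 1.20 (adjusted p = 4.99e-14), with 3 of 24 up and 14 up when adjusted over the list alone. Skeletal muscle markers stood beside them at a median of -2.77 (adjusted p = 1.19e-13), with 0 of 20 down over all genes and 17 down when adjusted over the list alone. Granulocyte precursor markers reached a median of 0.23 (adjusted p = 0.00706), with Lcn2 at 2.90 ± 0.58.

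At day 7, 419 genes rose and 283 fell in NTHi arrays against untreated ones, where 4118 had an unadjusted p under 0.05 and 5669 (31.2%) did not overlap, against 10% by chance. Saa3 rose by 7.18 ± 0.65 (adjusted p = 3.48e-04), to a level of 12.77 ± 0.57 (SD, n = 3), and Cxcl2 by 5.43 ± 0.50 (adjusted p = 3.48e-04). Acod1 rose by 6.13 ± 0.89, Slfn4 by 6.08 ± 0.70 and the lectin receptor Clec4e by 5.55 ± 0.88. Cxcl10, an interferon-induced chemokine, rose by 5.35 ± 1.08, and Msr1, a macrophage scavenger receptor, by 5.28 ± 0.83. Clec4d, Ccl3 and Cd300lf rose by 4.98, 4.88 and 4.75. The 10 largest falls were genes of muscle contraction and energy supply: Ckm -4.69 ± 0.94, Ckmt2 -4.64, Acta1 -4.39, Tnnt3 -4.24, Pvalb -4.05, Tnni2 -3.90, Myot -3.82, Atp2a1 -3.79, Mb -3.79 and Pgam2 -3.60. Mb had 1 of 2 probe sets in its direction. In each of these 20 genes the 3 NTHi arrays and the 3 untreated arrays did not overlap, as the rule for naming genes required.

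Of the lists at day 7, 17 passed, 14 upward, and none held, the smallest being adjusted p = 0.201 with an estimated correlation, while fry passed 11 lists. Interferon response genes had 11 of 27 members that rose (median 2.34, adjusted p = 2.33e-19), among them Cxcl9 by 4.11 ± 0.89, and 22 up when adjusted over the list alone. Monocyte and macrophage markers had 11 of 19 up (median 2.42, adjusted p = 1.22e-13) and 15 up when adjusted over the list alone. Mature neutrophil markers had 6 of 13 up (median 2.82, adjusted p = 6.72e-10), Fpr2 by 4.31 ± 0.87. Monocyte and lymphocyte chemokines had 11 up and 1 down of 20 (median 2.82, adjusted p = 6.72e-10). Toll-like receptor and NF-kB feedback genes had 6 of 28 up (median 1.09, adjusted p = 2.35e-11), Tlr2 by 2.69 ± 0.56 and Tlr6 by 2.17 ± 0.43, while Tlr4 was at 1.09 ± 0.31 (adjusted p = 0.0664). Complement genes had 6 of 14 up (median 1.25, adjusted p = 1.36e-04), with Cfp at 4.15 (1 of 2 probe sets upward) and C3ar1 at 3.97. The list of MHC class II and antigen presentation genes had 2 of 14 up (median 0.92, adjusted p = 1.78e-06), the integrin Itgax by 1.94 and the costimulatory ligand Cd86 by 1.42, and T and NK cell markers 2 of 16 (median 0.51, adjusted p = 2.73e-04), Gzmb by 3.36 and Cd3d by 1.23.

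Mucin and goblet cell genes moved the other way (median -0.43, adjusted p = 0.00254; adjusted p = 0.353 with an estimated correlation), with 2 of 24 that fell and 7 that fell, beside 1 that rose, when adjusted over the list alone. Fcgbp, a mucus-associated protein, fell by 1.68 ± 0.40 and the trefoil factor Tff1 by 1.36 ± 0.29. Muc5b was at -2.23 ± 0.65 (adjusted p = 0.0688), Muc5ac at -1.53 ± 0.71 (adjusted p = 0.221) and Muc4 at -0.63 ± 0.33. The secretoglobin Scgb3a1 fell by 1.47 ± 0.34 and the cilia gene Spag16 by 1.69 ± 0.42 (motile cilia list median -0.70, adjusted p = 3.85e-04; adjusted p = 0.599 with an estimated correlation). The mast cell proteases Cpa3 and Cma1 fell by 1.86 and 1.22, while their list of 15 markers did not pass (median -0.16, adjusted p = 0.296). Skeletal muscle markers had 13 of 20 that fell (median -3.40, adjusted p = 2.35e-11; adjusted p = 0.256 with an estimated correlation), and this fall accompanied each of these groups. Against the saline day 7 arrays of low cre level, Muc5b, Muc5ac and Muc4 were at -0.93, -0.26 and 0.11, none past the threshold. NTHi against untreated arrays holds lysate, inoculation and time together and cannot separate them. Quantile normalization gave 303 rises and 129 falls (70.1% higher, against 59.7%). It ended 10 of 48 calls among the named genes with little change in size: Spag16 (-1.55), Cma1 (-1.13), Mb (-3.59), Cd86 (1.42), Tnf (2.70 before, 2.60 after), Lcn2 (2.39 and 2.38), Mmp8 (3.06 and 2.99), Hk2 (1.75 and 1.74), Blnk (1.42 and 1.46) and Erbb3 (-0.89 and -0.78).

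The count at day 7 against untreated arrays rested on single arrays. It was 1911 without NTHi day 7 replicate 1, where the balance turned to 817 rises and 1094 falls, 7 without replicate 2 and 69 without replicate 3, and 58, 74 and 27 without untreated replicates 1, 2 and 3. Saa3 and Cxcl2 stayed past the threshold in each of these 6 fits, with changes of 6.88 to 7.54 and 5.31 to 5.58, while Ckm passed in 2 of them. With the muscle level as a covariate the count was 0, and without the saline day 7 group in the fit it was 756. In the fit with the covariate the SEs were wider. Saa3 was then at 6.13 ± 1.01, Acod1 at 6.29 ± 1.46, Cxcl2 at 4.87 ± 0.80, Msr1 at 4.37 ± 1.33 and Il1b at 3.38 ± 1.07. Array weights also turned the balance, to 1520 rises and 2919 falls.

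**Figure D2:**
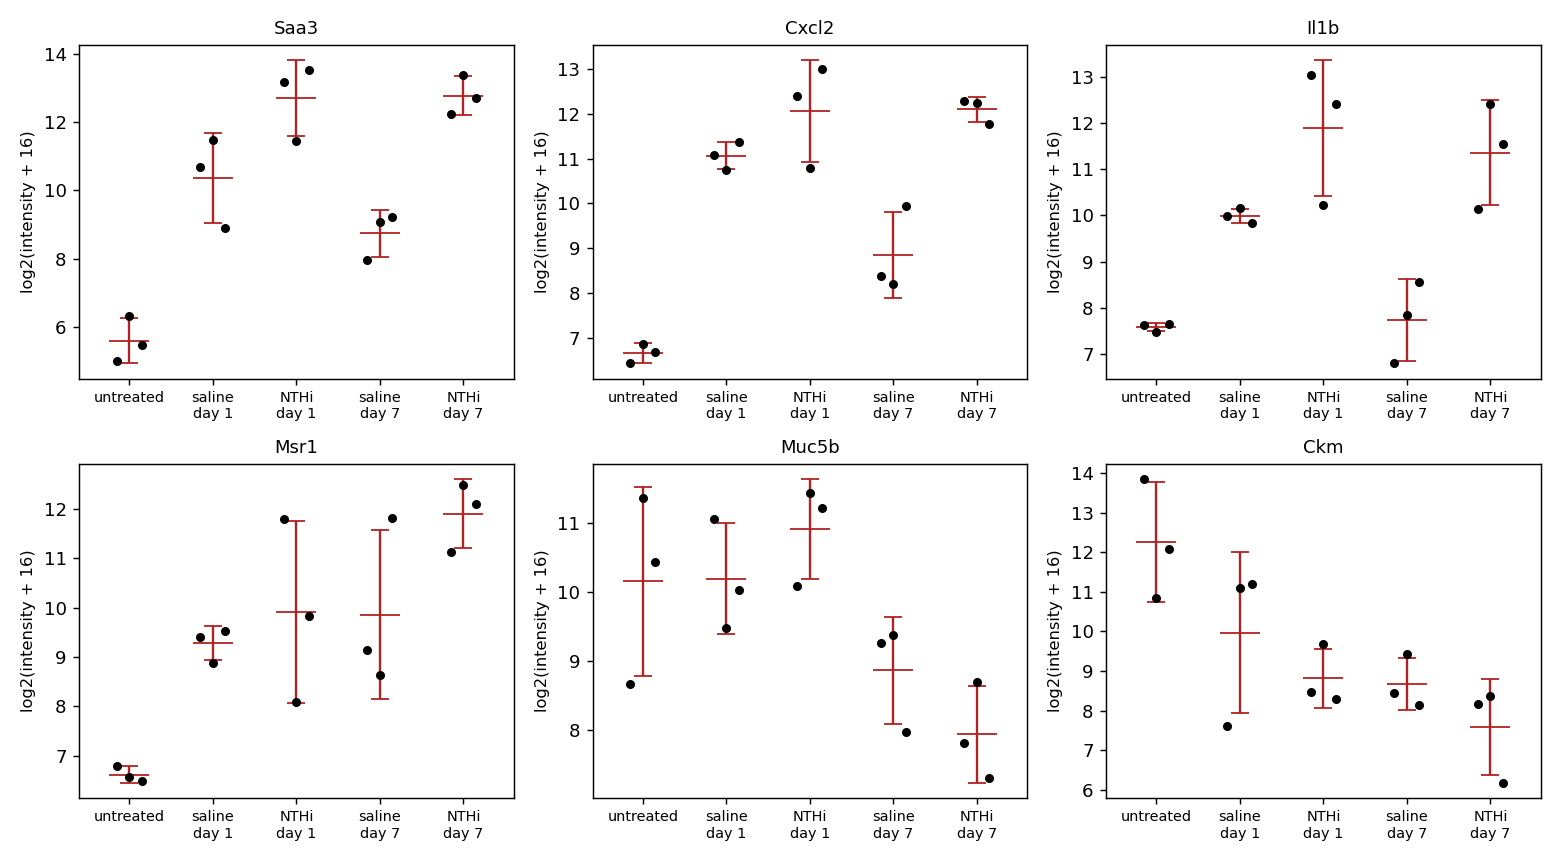
Levels of 6 genes, log2(intensity + 16), on each array. Points are arrays, and red bars are the group mean ± SD (n = 3). Saa3 and Cxcl2 are at 12.77 ± 0.57 and 12.10 ± 0.28 on NTHi day 7 arrays and at 5.59 ± 0.67 and 6.67 ± 0.22 on untreated ones. Ckm falls from 12.26 ± 1.51 to 7.57 ± 1.21, and Muc5b, which did not pass, goes from 10.16 ± 1.37 to 7.93 ± 0.70.

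**Figure D3:**
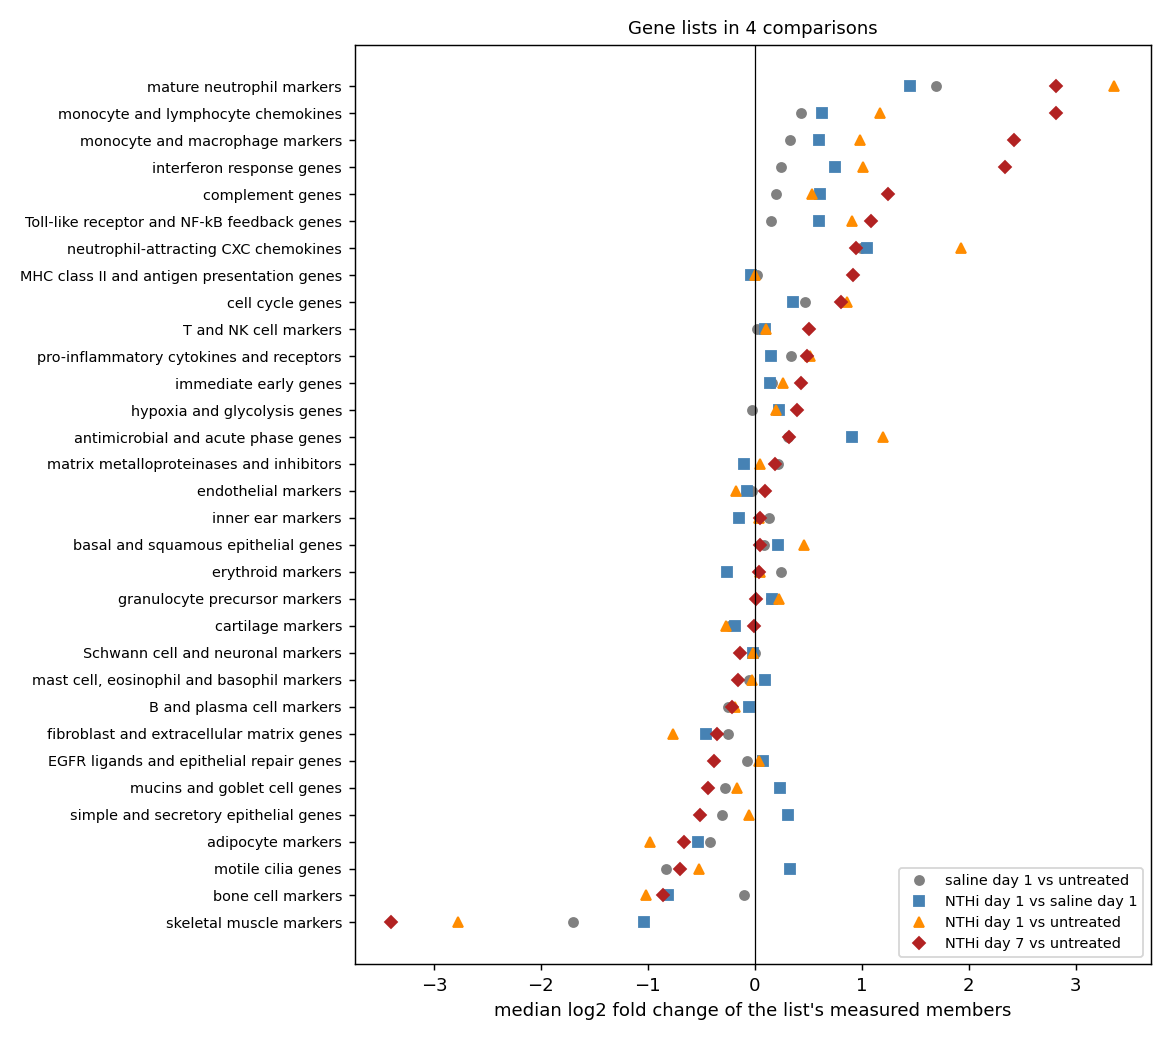
Median log2 fold change of the measured members of each of 32 gene lists in 4 comparisons, with 1 symbol per comparison. Mature neutrophil markers are at 1.70, 1.45, 3.36 and 2.82 in saline day 1 against untreated, NTHi day 1 against saline day 1, and NTHi day 1 and day 7 against untreated. Skeletal muscle markers are at -1.70, -1.03, -2.77 and -3.40.

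NTHi day 7 against saline day 7, the lysate effect at the later time, gave 4791 rises and 690 falls, with 7267 genes at an unadjusted p under 0.05 and 7580 genes (41.7%) without overlap, against 10% by chance. Saa3 rose by 4.03 ± 0.65 (adjusted p = 4.95e-04), from 8.74 ± 0.69 to 12.77 ± 0.57 (SD, n = 3). Il1b rose by 3.63 ± 0.66 (adjusted p = 0.00105), and Csf3r, the granulocyte colony-stimulating factor receptor, by 3.98 ± 0.76. The complement subunits C1qb and C1qc rose by 3.81 and 3.69, Acod1 by 3.86, Arg1 by 3.82, Rps15 by 3.70 and Cfp and Plac8 by 3.68 each. The largest falls were E2f5 -4.61 ± 0.24, Hdac11 -4.15 ± 0.31, Pik3cd -4.11 ± 0.19, Prl7a1 -4.01, Tbx5 -3.90, St8sia1 -3.88, Glra1 -3.71, Abcc12 -3.62, Tssk2 -3.53 and Gabrb1 -3.51. Other probe sets of several of these genes disagreed: 1 of 6 went down for Pik3cd, 1 of 3 for E2f5 and St8sia1, 1 of 2 for Hdac11 and Glra1, 2 of 3 for Prl7a1 and 2 of 4 for Gabrb1. E2f5, Pik3cd, Prl7a1 and Tbx5 were higher on saline day 7 than on untreated arrays, by 4.18, 4.13, 3.97 and 3.98. Their falls thus match a rise of the control arrays and need not be a lysate effect. Among the rises, Rps15 was lower on saline day 7 than on untreated arrays, by 3.78. Its rise of 3.70 thus matches a fall of the control arrays and need not be a lysate effect either.

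The control arrays of this comparison are those with the low cre level and the steep actin difference given above. The median change of all genes was 0.29, and quantile normalization, which removes that shift, gave 1608 rises and 1535 falls (51.2% higher, against 87.4%). All 1608 were among the 4791 rises, and 645 of the 1535 falls were among the 690. Relative to the median gene, Saa3 rose by 3.75, Csf3r by 3.70, C1qb by 3.52, Il1b by 3.34 and Cxcl2 by 2.96, and after quantile normalization by 3.32, 3.81, 3.34, 3.11 and 2.50, each still past the threshold. It ended 19 of 68 calls among the named genes, among them Tlr2 (1.80 before, 1.26 after), Tlr4 (1.11 and 0.37), S100a8 (2.61 and 1.58) and Agr3 (1.24 and 0.31).

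Against saline at day 7, 13 lists passed, 11 upward, and none held, the smallest being adjusted p = 0.239 with an estimated correlation. Of the inflammatory lists, Toll-like receptor and NF-kB feedback genes had 21 of 28 members up and 22 up when adjusted over the list alone (median 1.36, adjusted p = 9.24e-04), with Cd14 at 2.62 ± 0.33 and Ptgs2, the inducible cyclooxygenase, at 2.58 ± 0.86. Quantile normalization left Cd14 at 1.52 and ended the call of Ptgs2, then at 2.35. Interferon response genes had 17 of 27 up and 21 up when adjusted over the list alone (median 2.17, adjusted p = 9.24e-04), with Cxcl9 at 3.42 and Iigp1 at 3.34. Monocyte and macrophage markers had 13 of 19 up, or 16 when adjusted over the list alone (median 2.26, or 1.31 after quantile normalization, adjusted p = 0.00175). Antimicrobial and acute phase genes had 12 of 24 up and 1 down, or 14 and 1 when adjusted over the list alone (median 1.82, or 0.82 after quantile normalization, adjusted p = 0.00530), with Lcn2 at 3.53 ± 0.58. Complement genes had 9 of 14 up, or 12 when adjusted over the list alone (median 1.94, adjusted p = 0.00905). Mature neutrophil markers had 9 of 13 up, or 11 when adjusted over the list alone (median 1.94, adjusted p = 0.0231), with S100a9 at 2.89. Monocyte and lymphocyte chemokines had 10 of 20 up, or 14 when adjusted over the list alone (median 2.27, adjusted p = 0.0453), with Ccl8 at 3.20, a call that quantile normalization ended at 2.42.

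Cell cycle genes had 9 of 26 up under either adjustment (median 0.93, adjusted p = 0.0311), with Pcna at 2.36 and Mcm6 at 1.92. This call and those of the lists below ended as well, the smallest at adjusted p = 0.239 with an estimated correlation, while fry passed 18 lists in all. Simple and secretory epithelial genes had 13 of 21 up (median 1.62, adjusted p = 0.00304), with Sftpd at 3.03 and Cldn3 at 2.98. Immediate early genes had 11 of 19 up (median 1.13, adjusted p = 0.0146), with Ier3 at 2.33 and Zfp36 at 2.16, and hypoxia and glycolysis genes 9 of 17 (median 1.31, adjusted p = 0.0199), with Aldoa at 2.24 and Ldha at 1.98. Mast cell, eosinophil and basophil markers had 4 of 15 down (median -0.08, adjusted p = 0.00571), with Cpa3 at -1.33 and Fcer1a at -1.23. Skeletal muscle markers had 0 of 20 past the threshold (median -0.70, adjusted p = 0.00304; Myh4 at -1.64). Quantile normalization ended the calls of these last 5 lists, whose medians became 0.45, 0.21, 0.51, -0.20 and -1.07, and of Ldha, then at 0.66, and left Aldoa at 1.08, Pcna at 1.52 and Ier3 at 1.48.

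The other 19 lists did not pass at day 7 against saline, at adjusted p = 0.0685 to 0.990. MHC class II and antigen presentation genes had 7 of 14 up, H2-Ab1 by 2.69 and Cd74 by 2.54, and T and NK cell markers 7 up and 1 down of 16. These lists passed after quantile normalization, with medians of 0.91 and 0.72. Pro-inflammatory cytokines and receptors had 5 up and 1 down of 26, Ltb by 2.34, with Tnf at 1.61 ± 0.70 (adjusted p = 0.100) and Il6 at 0.52 ± 0.67. The neutrophil-attracting CXC chemokines and receptors had 1 of 7 up, Cxcl2 by 3.24 ± 0.50, with Cxcl1 at 0.91 ± 0.66. Fibroblast and matrix genes had 7 of 22 up (Sparc 2.52), metalloproteinases and inhibitors 6 of 18 (Mmp14 2.33), basal and squamous genes 4 of 21 (Lgals7 2.89), motile cilia genes 5 of 28 (Tppp3 2.90), endothelial markers 4 of 15 (Cdh5 1.36), B and plasma cell markers 3 of 16 (Xbp1 1.68), and granulocyte precursor markers 2 of 12. Cartilage markers had 3 up and 1 down of 12, EGFR ligands and epithelial repair genes 2 up and 1 down of 17 (the integrin Itgb6 at 1.25), Schwann cell and neuronal markers 2 of 12 up, inner ear markers 1 of 15, erythroid markers 1 of 14 down (Hba-a2 -1.37), and bone and adipocyte markers 0. Quantile normalization ended the calls of Cdh5 (0.48) and Xbp1 (0.22) and left Cd74 at 1.66, Sparc at 1.65 and Tppp3 at 1.89. Mucin and goblet cell genes had 1 of 24 up (Agr3), with Muc5b at -0.93 ± 0.65, Muc5ac at -0.26 ± 0.71 and Muc4 at 0.11 ± 0.33. Their test pointed downward while median (0.11) and mean (0.22) were positive, and the tests of bone, erythroid, cartilage, Schwann cell, epithelial repair, B cell and inner ear lists also opposed positive medians.

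The difference between the lysate effects at day 7 and day 1 was tested directly, and it holds the saline day 7 arrays of low cre level. It was larger at day 7 for C1qb by 3.39 ± 0.77 (adjusted p = 0.0190), Vim by 3.22 ± 0.70 and C1qc by 3.09 ± 0.78, and for Syn2 by 3.54 ± 0.28 and Foxh1 by 3.09 ± 0.76. The largest negative differences were E2f5 -4.56 ± 0.34, Hdac11 -4.11, Pik3cd -3.89, Prl7a1 -3.82 and St8sia1 -3.66. Of the probe sets of E2f5, Prl7a1 and St8sia1, 1 of 3 went in that direction, and of those of Pik3cd 3 of 6. E2f5, Hdac11, Pik3cd and Prl7a1 were higher on saline day 7 than on saline day 1 arrays, by 4.21, 3.81, 3.86 and 3.77. Their negative differences thus match a rise between the control groups. Syn2 and Foxh1 were lower on saline day 7 than on saline day 1 arrays, by 3.76 and 3.16. Their positive differences thus match a fall between the control groups and need not be a lysate effect. In all 1155 genes had a higher and 204 a lower effect at day 7, with 4209 at an unadjusted p under 0.05 and a median of all genes of 0.29. Relative to that median the differences were 3.10 for C1qb, 2.93 for Vim and -4.85 for E2f5. Saa3 had a difference of 1.67 ± 0.92 (adjusted p = 0.302), Il1b of 1.73 ± 0.93 (adjusted p = 0.289), Cxcl2 of 2.25 ± 0.71 (adjusted p = 0.0707) and Muc5b of -1.66 ± 0.92 (adjusted p = 0.303). Monocyte and macrophage markers differed as a list (adjusted p = 0.0482, medians 0.60 and 2.26; adjusted p = 0.936 with an estimated correlation), with 5 of 19 members higher at day 7 and 6 when adjusted over the list alone. Immediate early genes also did (adjusted p = 0.0482, medians 0.14 and 1.13), with 3 of 19, as did mast cell, eosinophil and basophil markers downward (adjusted p = 0.00400, medians 0.10 and -0.08), with 1 of 15. The smallest of these values, of the mast cell list, was adjusted p = 0.0841 with an estimated correlation, and the others were at adjusted p = 0.936 with an estimated correlation. Quantile normalization gave 61 higher and 180 lower genes (25.3% higher, against 85.0%), and left C1qb at 3.02, Foxh1 at 2.93, C1qc at 2.62 and Vim at 2.39, no longer past the threshold. It also ended the call of the immediate early list, whose median difference went from 0.97 to 0.31, while those of the monocyte and macrophage list and the mast cell list went from 1.41 to 0.70 and from -0.21 to -0.37. Without saline day 1 replicate 3, saline day 7 replicate 1 or 2, NTHi day 1 replicate 1 or NTHi day 7 replicate 2 the count was 625, 627, 889, 840 or 678. The number of lists was 1 without saline day 1 replicate 2 or 3, saline day 7 replicate 1 or NTHi day 7 replicate 2. It was 6 without saline day 1 replicate 1, 8 without NTHi day 7 replicate 1, 9 without saline day 7 replicate 3 and 10 without NTHi day 1 replicate 1.

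The lysate effects at day 1 and day 7, which share no array, had a correlation of r = 0.44 (rho = 0.445) across the 18193 genes, with the same sign in 63.7%. Genes are not independent replicates. The day 7 effect also holds the saline day 7 arrays of low cre level. Mean 5′ minus 3′ actin was lower on saline than on NTHi arrays at day 1 (-2.15 against -1.12, with overlap) and day 7 (-4.83 against -1.29). Whether this contributed to the correlation was not tested. No gene passed at day 1, so the overlap of called genes was 0.

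Saline day 7 against untreated arrays gave 610 rises and 5765 falls, with 8059 genes at an unadjusted p under 0.05, 9462 (52.0%) without overlap against 10% by chance, and a median change of all genes of -0.37. Saa3 rose by 3.15 ± 0.65 (adjusted p = 0.00222) and Cxcl2 by 2.18 ± 0.50 (adjusted p = 0.00415), while Il1b was at 0.15 ± 0.66. E2f5, Pik3cd, Tbx5 and Prl7a1 rose by 4.18, 4.13, 3.98 and 3.97, although 1 of 3 probe sets did so for E2f5 and for Prl7a1. Tpsg1, Syn2, Rps15 and Tnni2 fell by 4.08, 3.89, 3.78 and 3.78, Syn2 in 3 of 6 probe sets. Simple and secretory epithelial genes had 17 of 21 down (median -1.90, adjusted p = 1.61e-04), motile cilia genes 19 of 28 (median -1.51, adjusted p = 0.0143) and skeletal muscle markers 14 of 20 (median -2.58, adjusted p = 0.0430), calls that ended, each at adjusted p = 0.967 with an estimated correlation. After quantile normalization the medians of the simple and secretory and the cilia genes were -0.72 and -0.83. Mature neutrophil markers moved upward relative to the other genes (median 0.63, adjusted p = 0.0143), as did interferon response genes, monocyte and lymphocyte chemokines and pro-inflammatory cytokines and receptors, 4 calls that quantile normalization ended. All 7 calls ended with an estimated correlation (each at adjusted p = 0.967 with an estimated correlation), and fry passed 11 lists. Quantile normalization gave 1124 rises and 1383 falls (44.8% higher, against 9.57%), of which 547 rises and all 1383 falls were among those above. Relative to the median gene, E2f5 rose by 4.55 and Pik3cd by 4.50, and Tpsg1 fell by 3.71. The low cre level and steep actin difference of the saline day 7 arrays moved with all of these groups. Leaving out untreated replicate 1 gave 11 lists and saline day 7 replicate 3 gave 1.

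Saline day 7 against saline day 1 followed the controls over time, with the same arrays of low cre level. Cxcl2 fell by 2.21 ± 0.50 (adjusted p = 0.00667), Lcn2 by 2.77 ± 0.58, Il1b by 2.26 ± 0.66 and S100a8 by 2.08 ± 0.57, against a median of all genes of -0.27. In the fit that kept only the brighter probe sets the median was -0.44, so brighter genes shifted further down. How much of these 4 falls such a shift accounts for was not tested. Scube1, Syn2, Foxh1 and Lrtm2 fell by 3.88, 3.76, 3.16 and 3.00, and E2f5, Pik3cd, Hdac11 and Prl7a1 rose by 4.21, 3.86, 3.81 and 3.77. In their direction went 1 of 3 probe sets of Foxh1 and of E2f5, 2 of 6 of Pik3cd and 1 of 2 of Hdac11. Relative to the median gene, Scube1 fell by 3.62 and E2f5 rose by 4.48. There were 375 rises and 3207 falls, with 5941 genes at an unadjusted p under 0.05 and 6274 (34.5%) without overlap, against 10% by chance. Quantile normalization gave 672 rises and 780 falls (46.3% higher, against 10.5%), and the count without saline day 7 replicate 1 was 2062.

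NTHi day 7 against NTHi day 1 compared the lysate arrays with each other. Muc5b, the gel-forming mucin, was at -2.99 ± 0.65 (adjusted p = 0.252), from 10.92 ± 0.73 at day 1 to 7.93 ± 0.70 at day 7 (SD, n = 3), and all 3 later arrays were lower. Saa3, Cxcl2 and Il1b were at 0.06, 0.03 and -0.53. MHC class II and antigen presentation genes (median 1.27, adjusted p = 4.01e-09), interferon response genes (median 0.99, adjusted p = 4.01e-09) and monocyte and macrophage markers (median 1.16, adjusted p = 7.58e-08) moved upward as lists, calls that ended at adjusted p = 0.348 or above with an estimated correlation. Simple and secretory epithelial genes (median -0.41, adjusted p = 4.31e-06), mucin and goblet cell genes (median -0.29, adjusted p = 2.49e-05) and antimicrobial and acute phase genes (median -0.47, adjusted p = 6.95e-05) moved downward. These were among 17 lists that passed, all of which ended at adjusted p = 0.348 or above with an estimated correlation, and fry passed 0. No single gene passed in limma; 1317 had an unadjusted p under 0.05 and 1740 (9.56%) did not overlap, against 10% by chance. The count was 26 without NTHi day 7 replicate 1, 2 without replicate 3, and 1 without NTHi day 1 replicate 1 or 2.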

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

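The tests on the saline day 7 arrays, on NTHi day 1 replicate 2 and on a lower muscle share were chosen only after the result was seen, as was the fit with the muscle level.

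The difference between the lysate effects at day 7 and day 1, tested as an interaction term, passed for 1359 genes. Of 112 genes named in the comparisons of lysate with saline, 29 were among them, 18 with a higher effect at day 7. Quantile normalization left 61 genes with a higher and 180 with a lower effect at day 7, and of these 29 it kept 13 past the threshold: all 11 lower ones and, of the higher ones, Cldn3 (2.02) and Rps15 (2.38). The other 16 no longer passed. Some shrank strongly, with Col1a2 at 1.16, Cdh5 at 0.64, Ldha at 0.55 and Xbp1 at 0.11. Others kept more of their size, with C1qb at 3.02, C1qc at 2.62, H2-Ab1 at 2.11, Sparc at 2.10 and Cd74 at 1.82. On the deposited scale, the differences in immune and antigen presentation genes were 3.39 for C1qb, 3.09 for C1qc, 2.90 for H2-Ab1, 2.58 for Cd74 and -1.05 for Fcer1a. Those in epithelial, matrix and vessel genes were 2.85 for Sparc, 2.53 for Col1a2, 2.48 for Cldn3, 2.43 for Tppp3, 2.13 for Mmp14, 1.73 for Tubb4b and 1.40 for Cdh5. Other genes higher at day 7 were Rps15 (2.97), Aldoa (2.00), Pcna (1.94), Ier3 (1.81), Ldha (1.73), Xbp1 (1.45) and Nkd2 (1.35). The lower ones were E2f5 (-4.56), Hdac11 (-4.11), Pik3cd (-3.89), Prl7a1 (-3.82), St8sia1 (-3.66), Tbx5 (-3.59), Tssk2 (-3.49), Glra1 (-3.46), Gabrb1 (-3.37) and Abcc12 (-3.21). For E2f5, Hdac11, Pik3cd and Prl7a1 these match rises of 4.21, 3.81, 3.86 and 3.77 in saline day 7 against saline day 1 arrays. Rps15, among the higher ones, was lower by 3.78 on saline day 7 than on untreated arrays, so its day 7 rise need not be a lysate effect. As lists, monocyte and macrophage markers (adjusted p = 0.0482), immediate early genes (adjusted p = 0.0482) and mast cell, eosinophil and basophil markers (adjusted p = 0.00400) differed. None held, the smallest being adjusted p = 0.0841 with an estimated correlation, and quantile normalization ended the call of the immediate early genes.

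The saline day 7 arrays, the controls of the later lysate effect, differed from untreated arrays in 6375 genes, most of them lower. A tissue response to saline is argued against as the whole cause: the highest saline day 7 array differed from the lowest other array by -0.72 in the log2 level of the cre spike-in, RNA that the animals did not make; bioD was also apart, while the dimmer bioB and bioC overlapped. A monotone intensity shift of whole arrays is also argued against as the whole cause, since quantile normalization, which removes such a shift, kept 30.3% of the calls in their direction. Shorter amplified RNA remains a candidate explanation for a part, with a gap of -0.98 to the nearest other array in 5′ minus 3′ actin. A response of the tissue to saline or to time in another part stays open and was not separated from it.

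NTHi day 1 replicate 2 lay below the other 2 NTHi day 1 arrays in inflammatory genes, with a pro-inflammatory score of -0.24 against 0.78 and 0.56, and without it 4 genes passed against saline and 97 against untreated arrays. A swap with a saline day 1 array is argued against only for a mouse that responded as strongly as these other 2. The highest saline array stayed below both of them (gap -0.36). The test cannot exclude a swap with a mouse of weaker response, because scores varied within the NTHi groups. An untreated mouse under this label is argued against by its antimicrobial score, 0.70 above the highest untreated array. Its pro-inflammatory score differed from the highest saline day 1 array by -0.44 and lay below the lowest (-0.12), outside the range set for a saline mouse or a weaker delivery, by less than the saline arrays spread. Its antimicrobial score (0.32) lay beside the highest saline one (0.30), so these 2 explanations stay open and cannot be told apart with 3 arrays per group. The pattern was not limited to this array. NTHi day 7 replicate 1 had a pro-inflammatory score of -0.25, against 1.21 and 0.37 on replicates 2 and 3 of its group, and was not tested in this way.

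In NTHi day 7 against untreated arrays, monocyte and macrophage markers were higher (median 2.42) and skeletal muscle markers lower (median -3.40). A lower muscle share alone would raise the markers of all other cell types alike, and the lower quartile of the macrophage markers lay 0.56 above the highest upper quartile of the endothelial, fibroblast, Schwann cell, bone and cartilage lists. In the fit with the muscle level the median was 2.24 (quartiles 1.47 to 2.99), against 2.42 (quartiles 1.09 to 3.03) without it. The muscle scores were 0.73 to 3.15 on untreated and -1.82 to -0.70 on NTHi day 7 arrays. As they do not overlap, the fit extrapolates and does not decide whether a trend with the muscle level is the whole cause. That fit left 0 genes past the threshold in limma, since the muscle level follows the groups and the median SE of these markers widened from 0.546 to 0.850; Saa3 went from 7.18 ± 0.65 to 6.13 ± 1.01. Arrival of myeloid cells or a change within resident cells may each explain the rise, and neither was tested.

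Other splits of the samples were counted for each comparison, with the real split included. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. Where the real count is 0, every split calls as many, so the result of 10 splits was fixed in advance. As many genes as in the real split were called in 10 splits for NTHi against saline at day 1 (0 real, highest other 1), 1 at day 7 (5481, highest other 410), 2 for saline day 1 against untreated (3, highest other 5), 1 for saline day 7 against untreated (6375, highest other 5), 1 for saline day 7 against saline day 1 (3582, highest other 1), 1 for NTHi day 1 against untreated (11, highest other 0), 1 for NTHi day 7 against untreated (702, highest other 1) and 10 for NTHi day 7 against NTHi day 1 (0, highest other 764). The last split exchanged replicates 2 and 3 of the 2 groups and called many genes, which points to a structure of the samples. As many lists were called in 3 splits for NTHi against saline at day 1 (17, highest other 19), 5 at day 7 (13, highest other 16), 2 for saline day 1 (15, highest other 18) and 9 for saline day 7 (7, highest other 19) against untreated, and 2 for NTHi day 1 (19, highest other 24) and 4 for NTHi day 7 (17, highest other 21) against untreated.

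For the difference between days, 14 of 100 splits called as many genes as the real 1359 (highest other 6058), and 99 of 100 as many lists as the real 3 (highest other 23), so chance could not be excluded. All 14, the real split among them, kept the 3 saline day 7 arrays together. This also kept the 3 NTHi day 7 arrays together. Splits that parted them called at most 68 genes. The count thus follows the day 7 grouping and cannot tell a lysate effect from a trait of the saline day 7 arrays. Because 14 of the 100 splits hold that grouping, a share under 0.05 was out of reach for genes that differ by it.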

How the results depend on the processing

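The fits without the saline day 7 group and with the muscle level, and all alternatives for NTHi against untreated, were chosen only after the data were seen. Over 266 pairs of a named gene and a comparison, 4000 alternative values were computed. Of those of called genes, 1916 kept direction and side of the threshold, 447 kept the direction and lost the call, and 0 changed sign. Of the others, 1588 stayed, 29 passed and 20 changed sign. The cause was not tested for any change below unless named. A lone left-out array leaves 2 in its group. Dim genes lie near the floor of 4, where changes are understated.

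Quantile normalization gave 3143 genes for NTHi against saline at day 7, 241 for the difference between days, 1 for saline day 1, 2507 for saline day 7, 6 for NTHi day 1 and 432 for NTHi day 7 against untreated, and 1452 for saline day 7 against saline day 1. It gave 7 lists for the difference between days and 3 for saline day 7 against untreated, and a common median also gave 7 and 3.

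An offset of 1 gave 1 list for the difference between days and a correlation of 0.345 between the lysate effects at day 1 and day 7. Keeping the brighter probe sets gave 8 lists for NTHi against saline at day 7 and 0 for the difference between days. Array weights gave 2164 genes for the difference between days, 1721 for saline day 1 against untreated (321 higher) and 111 for NTHi day 7 against NTHi day 1. For NTHi against untreated they gave 172 (94 higher) at day 1 and 4439 (1520 higher) at day 7. The mean of probe sets gave 746 genes and 6 lists for the difference between days and 5 genes for NTHi day 1 against untreated.

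Per probe set, with more units tested, there were 10393 for NTHi against saline at day 7, 2419 for the difference between days, 1 and 11463 for saline against untreated at day 1 and day 7, and 6584 for saline day 7 against saline day 1. With only the compared groups in the fit there were 754 genes for the difference between days, 19 for saline day 1 against untreated, 2361 for saline day 7 against saline day 1 and 6 for NTHi day 1 against untreated. Without the saline day 7 group, NTHi day 1 against untreated gave 7. With the muscle level in the fit, NTHi against untreated gave 0 at day 1 and 0 at day 7. A change of at least 2-fold, a stricter threshold, left 3083 genes for NTHi against saline at day 7, 3625 for saline day 7 against untreated and 1902 against saline day 1.

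Camera with an estimated correlation called 0 lists in NTHi against saline at day 1 and day 7, in the difference between days, and in saline and NTHi against untreated at day 1 and day 7. Fry called 0 lists for NTHi against saline at day 1, 0 for the difference between days, 0 for saline day 1, 11 for saline day 7, 3 for NTHi day 1 and 11 for NTHi day 7 against untreated.

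With each array left out in turn, genes numbered 0 to 4 for NTHi against saline at day 1, 3686 to 5519 at day 7, 625 to 1957 for the difference between days, 0 to 6 and 4546 to 5892 for saline against untreated at day 1 and day 7, 0 to 26 for NTHi day 7 against NTHi day 1, 2062 to 3421 for saline day 7 against saline day 1, and 3 to 97 and 7 to 1911 for NTHi against untreated at day 1 and day 7. Lists numbered 14 to 21 for NTHi against saline at day 1, 9 to 15 at day 7, 1 to 10 for the difference between days, 11 to 17 and 1 to 11 for saline against untreated, and 16 to 19 and 17 to 20 for NTHi against untreated. The correlation between the lysate effects ranged from 0.345 to 0.442 (SD 0.0321).

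The values that changed sign belonged to genes that were not called. Muc4 in NTHi against saline at day 7 was at -0.00414 with a common median, -0.00592 with array weights and -0.37 with the mean of probe sets, and ranged from -0.0593 (without NTHi day 7 replicate 2) to 0.29 with 1 array left out. Muc5ac there ranged from -0.66 to 0.25 (without saline day 7 replicate 1). In NTHi against saline at day 1, array weights gave -0.57 for Alas2 and 0.51 for Il6. With 1 array left out, Alas2 ranged from -1.01 (without saline day 1 replicate 3) to 1.88, Il6 from -0.80 to 0.72 (without NTHi day 1 replicate 2), Muc5ac from -0.23 (without saline day 1 replicate 3) to 0.96, Gzmb from -0.16 (without NTHi day 1 replicate 1) to 0.91 and Ucp1 from -3.34 to 0.0216 (without saline day 1 replicate 2). In NTHi day 1 against untreated, Muc4 was at -0.13 with array weights and from -0.16 (without untreated replicate 1) to 0.53 with 1 array left out, and Muc5ac from -0.76 to 0.62 (without untreated replicate 2).

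Replicate numbers did not pair the arrays: arrays of different groups with the same number correlated at a mean r of -0.04 (30 pairs, -0.55 to 0.38) and those with different numbers at 0.02 (60 pairs). With a block for the number, the counts were 6 lists for the difference between days, 1 gene for saline day 1 against untreated, and 6 and 383 genes for NTHi against untreated at day 1 and day 7.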

Other observations

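These values were picked after they were seen and were not tested further. Scgb3a1 was at 11.30 or higher on all 3 NTHi arrays at day 1 and at 9.62, 9.50 and 8.70 at day 7, with untreated arrays at 10.21, 11.19 and 10.84 and saline day 7 arrays at 9.27, 9.89 and 8.87. Tff1 was at 8.25, 9.33 and 8.63 on NTHi arrays at day 1 and at 7.29, 7.85 and 6.80 at day 7, with untreated arrays at 8.53, 8.79 and 8.70, within the range of day 1, and saline day 7 arrays at 7.91, 8.01 and 7.79, also below every untreated array. Cyp2f2, another secretory gene, overlapped between the 2 days (12.90, 13.48 and 13.27 at day 1, and 13.40, 12.94 and 13.01 at day 7).

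Kera, the matrix proteoglycan, was at 8.89, 8.73 and 9.08 on untreated arrays and at 7.79, 9.70 and 9.68 on saline day 1 arrays. It was at 6.34, 6.23 and 6.94 on NTHi day 1 arrays and at 6.00, 5.96 and 5.32 on NTHi day 7 arrays, below every untreated array. Saline day 7 arrays had 6.37, 7.67 and 7.22.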
